A study of Mus musculus with 6 samples.

How the data were processed

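Macrophages grown from mouse bone marrow cells were profiled by RNA sequencing in 6 libraries. Per the labels, the cells called TpMos and mature Ly6Chi monocytes were sorted from bone marrow and cultured for 7 days with CSF-1, the growth factor that maintains macrophages, and the resulting macrophages were scraped off for RNA. The 2 groups, TpMo-derived and Ly6Chi-derived macrophages, hold 3 libraries each. The protocol speaks of indicated CSF-1 concentrations, but the concentration of each sample is not given in the sources used here. Per the labels' protocols, total RNA with a RIN above 7.9 was used, and 2 ng of it went into each SMART-seq v2 library together with 1 µl of an ERCC spike-in mix diluted 50000-fold. Nextera XT tagmentation of 250 pg of cDNA was followed by paired-end sequencing of 51 cycles per read, with 14 samples per lane.

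The authors deposited raw read counts per gene in 1 table. Per the file header, featureCounts 1.6.3 counted aligned reads over exons of the GENCODE M22 annotation, with no option for read pairs, strand, multi-mapped reads or reads that overlap several genes. By the defaults of that program, both mates of a pair were therefore counted as separate reads, strand was ignored, and reads that mapped to several places or fell on several genes were left out. A read pair can thus enter a gene as 2 counts, genes with near-identical copies lose reads, and sense and antisense reads cannot be told apart. STAR and the GRCm38 build come from the submitters' processing notes. The aligner's version is not given in the sources used here. The table lists 55487 genes, of which 33984 had no count in any library, and it holds 0 spike-in rows. Gene symbols, biotypes and GC content were taken from GENCODE M21 on the same build. Of the gene identifiers, 55394 matched and 93 did not and kept their identifier. Gene positions are those of the deposited table.

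The libraries held between 23765773 and 33042094 counts on genes. A floor of 3 counts then corresponds to 0.0908 to 0.126 CPM (counts scaled to the library total). It covers counting error only, since reads without molecular identifiers are not independent molecules. Because both mates of a pair were counted, it is also on the low side for counting error. Replicates were numbered in accession order, because the labels give no replicate number, batch or animal. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries were checked for duplicates with a chi-square comparison of their counts. Within groups the statistic per degree of freedom was 21.9 to 36.8, above counting error, which is all the statistic covers. No library is thus a copy of another's counts, but repeat libraries of 1 RNA sample would pass this check too.

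Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), libraries were scaled by TMM, and the robust quasi-likelihood test compared the groups with no covariate. p-values were adjusted by the Benjamini-Hochberg method over the 13140 genes tested, and an adjusted p under 0.05 counted as changed. A positive log2 fold change means higher in TpMo-derived macrophages. Standard errors (SE) were derived from the fold change and its F statistic. CPM values of genes were scaled to the TMM-adjusted totals over the genes tested, unlike the floor above, and are given as mean ± SD over 3 libraries. Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with adjustment over 29 lists, and again with an estimated correlation and with fry. Camera asks whether members change more than other genes do, and fry whether they change at all, so their calls differ in meaning. With an estimated correlation, camera also rests on the few residual degrees of freedom of the libraries. A call lost there is thus not by itself a sign of correlated members. A further 8 lists of markers of other cell types were described by their detected members and not tested as lists.

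The comparison, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Named whatever their values were Ly6c2, Ccr2, Cxcr4, Csf1r, Adgre1 and Mki67. The rule then took the 8 genes per direction with the largest fold change among changed genes with a mean of at least 5 CPM, no overlap between groups, and a symbol that is neither a clone name nor a pseudogene. In each list it took up to 4 changed members with the smallest p, and in each list that passed its test up to 2 members with the highest mean CPM. Together these made 151 genes, of which the text names those that describe a group best. Several abundant members that did not pass are therefore not named. Other genes are named only among the additional observations and were chosen after the data had been seen.

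The scripts were tested on simulated counts with the means and library sizes of the real samples. Among 13140 simulated genes, the edgeR test recovered 28.4% of those changed 1.5-fold, 43.3% of those changed 2-fold and 63.6% of those changed 4-fold, with 5 false calls. Of the changed genes with at least 5 CPM it recovered 37.3%, 60.4% and 93.2%. The simulation changed only 67, 67 and 66 genes by those folds, fewer than the 1620 called in the real data. The adjusted threshold is looser when more genes change, so these shares do not carry over to the real comparison. In the simulation a change of 2-fold or less was often missed. Alternatives were DESeq2 size factors, upper-quartile scaling, library sizes alone, the Wald test of DESeq2 1.42.0, limma-voom with and without quality weights, 2 other count filters, protein-coding genes only, a stricter threshold, a test against a 1.5-fold change and the removal of each library in turn. A correction for GC content and gene length, and the list test with library sizes alone, were added after the data had been seen.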

Results

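The data set compared macrophages grown for 7 days with CSF-1 from 2 kinds of sorted mouse bone marrow cell, TpMos and mature Ly6Chi monocytes, and so addressed how the macrophages that these cells give rise to differ. Each group held 3 libraries. TpMo-derived macrophages had total counts of 33042094, 27154105 and 23765773, and Ly6Chi-derived macrophages had 26804286, 27051518 and 31820999.

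TpMo-derived macrophages carried higher levels of interferon-induced, complement C1q and MHC class I transcripts and of Apoe, whereas Ly6Chi-derived macrophages carried higher levels of mitotic transcripts, of the macrophage elastase Mmp12 and of the integrin Itgax. Of 13140 genes tested, 1620 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 859 higher and 761 lower in TpMo-derived macrophages, whereas with library sizes alone the balance turned, with 737 higher and 902 lower. Among them, 290 were at least 2-fold higher and 307 at least 2-fold lower. The groups did not overlap for 4005 genes, or 30.5% of those tested, where chance gives 10%. The first principal component held 37.6% of the variance and separated the groups. Log2 CPM correlated at 0.943 to 0.947 across genes between TpMo-derived libraries, at 0.953 to 0.957 between Ly6Chi-derived libraries and at 0.920 to 0.932 between groups. The biological coefficient of variation was 31.7%. The count of changed genes fell to 317 in a test against a 1.5-fold change and to 785 at an adjusted p under 0.01. It rose to 2383 with the Wald test of DESeq2, 1207 higher and 1176 lower, with 21503 genes entering that test. The edgeR count was 1074 without TpMo-derived replicate 3, and 1058, 976 and 1062 without Ly6Chi-derived replicates 1, 2 and 3. Of 29 gene lists, 17 passed camera at its preset correlation and 0 with an estimated one (adjusted p from 0.0854, with 7 lists at an unadjusted p under 0.05). Fry, which asks whether members change at all, called 16. Splits of the libraries that mixed the groups gave up to 9 lists by camera at the preset, though such splits keep part of the group difference.

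**Figure D1:**
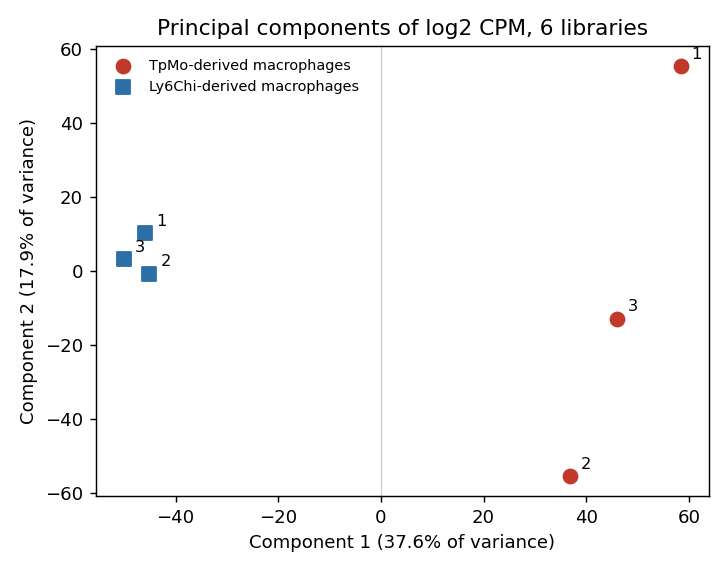
Scores of the 6 libraries on the first principal components of log2 CPM, with the share of variance in percent on each axis and the replicate number beside each point. The first component, with 37.6% of the variance, places the 3 TpMo-derived libraries (circles) on one side and the 3 Ly6Chi-derived libraries (squares) on the other.

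The rule above, with its mean of at least 5 CPM over all 6 libraries, gave 8 genes with the largest increases. They were the dicarboxylate transporter Slc13a3, the gelatinase Mmp9, the neighbouring genes Tmem176a and Tmem176b, the complement regulator Cd55, and the interferon-induced genes Ifi44, Ifit3 and Ifi213. In the Ly6Chi-derived group Tmem176a stood at 0.204 and Cd55 at 0.292 CPM. Like Slc13a3 and Mmp9 there, they lay near the floor, so the sizes of their fold changes are uncertain. Slc13a3 stood at 93.5 ± 36.9 CPM against 0.484 ± 0.544 CPM, a log2 fold change of 7.64 ± 0.59 (SE), or 9.07 without Ly6Chi-derived replicate 2. Mmp9 stood at 43.7 ± 17.2 CPM against 0.244 ± 0.423 CPM, where Ly6Chi-derived replicate 2 held all 20 counts of that group. Tmem176a and Tmem176b overlap on chromosome 6, where reads on both were not counted, and were 6.61 and 6.15 higher on the log2 scale, or 8.10 and 6.80 without Ly6Chi-derived replicate 3. Cd55 was 6.18 higher, or 7.45 without Ly6Chi-derived replicate 2, and Ifi44 5.19 higher, or 6.20 without Ly6Chi-derived replicate 3. The call of Tmem176a was lost with limma-voom (adjusted p = 0.0527), and that of Ifi44 without a count filter (adjusted p = 0.0604). The largest decreases were those of Trem1, Amz1, Cd33, Cd34, Tmem119, Itgax, Runx3 and Galnt9, with log2 fold changes from -3.68 to -2.93, where Runx3 moved from -3.05 to -3.66 without TpMo-derived replicate 3. Trem1, an activating receptor of myeloid cells, fell from 59.6 ± 13.5 CPM in Ly6Chi-derived to 4.62 ± 1.39 CPM in TpMo-derived macrophages. Itgax, which encodes CD11c, stood at 12.7 ± 3.97 CPM against 108 ± 13.2 CPM. The gene with the smallest p was Mmp12 (ENSMUSG00000049723.14, chromosome 9, 7344381 to 7369499 on GRCm38), at 989 ± 84.9 CPM against 6844 ± 597 CPM, with a log2 fold change of -2.79 ± 0.08 (SE, adjusted p = 1.26e-07).

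Genes of the type I interferon response were higher in TpMo-derived macrophages nearly without exception. Of 30 measured members, 28 rose, 0 fell and 2 did not pass, with a median log2 fold change of 2.22. Adjusted over the list alone, 30 rose. Ifit3 (ENSMUSG00000074896.3, chromosome 19, 34583531 to 34588731) stood at 229 ± 43.8 CPM against 7.31 ± 1.19 CPM (log2 fold change 4.97 ± 0.18 SE, adjusted p = 6.46e-07), the antiviral GTPase Mx1 at 37.7 ± 5.17 CPM against 4.58 ± 0.505 CPM, and Oasl2 at 306 ± 24.8 CPM against 89.9 ± 23.7 CPM. The list passed camera (adjusted p = 1.34e-27), but the call was lost with adjusted p = 0.113 with an estimated correlation. MHC class I presentation rose in 12 of 17 members and fell in 0, with a median log2 fold change of 0.64, and adjusted over the list alone in 12, with Tap1, a subunit of the peptide transporter, at 118 ± 7.07 CPM against 48.6 ± 3.25 CPM (list adjusted p = 2.55e-08, and adjusted p = 0.179 with an estimated correlation). Reads of Ifit3 and of the H2 genes are in part shared with near-identical family members, so their levels are uncertain. The MHC class II list did not pass (adjusted p = 0.759). Its members went both ways, with 3 higher and 3 lower of 13, and 6 higher and 4 lower adjusted over the list alone. The invariant chain Cd74 rose to 110.0 ± 48.5 CPM from 5.52 ± 3.21 CPM, and the thiol reductase Ifi30 fell to 38.2 ± 0.538 CPM from 80.8 ± 9.18 CPM. The calls of H2-Ab1 and H2-Aa, 3.61 and 4.37 higher on the log2 scale, were lost without a count filter (adjusted p = 0.134 and 0.0637), and H2-Aa was 5.38 higher without Ly6Chi-derived replicate 2.

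Mitotic genes were lower in TpMo-derived macrophages. Of 30 genes of the G2 and M phases, 25 fell, 0 rose and 5 did not pass, with a median log2 fold change of -1.32, and 29 fell adjusted over the list alone. The mitotic kinase Plk1 (chromosome 7, 122159439 to 122169873) stood at 21.3 ± 2.84 CPM against 76.3 ± 4.21 CPM, and the spindle motor Cenpe at 19.3 ± 2.44 CPM against 57.6 ± 11.7 CPM. Mki67, the proliferation marker, stood at 67.9 ± 26.9 CPM against 176 ± 30.8 CPM (log2 fold change -1.37 ± 0.24 SE, adjusted p = 0.0051, or 0.117 without a count filter). The list passed (adjusted p = 2.91e-16, and adjusted p = 0.263 with an estimated correlation). The S phase list did not pass (adjusted p = 0.159). Of its 26 members 2 rose and 3 fell, and adjusted over the list alone 3 rose and 6 fell. Pcna, the sliding clamp of DNA polymerases, rose to 507 ± 47.7 CPM from 331 ± 14.7 CPM, whereas Rrm2, a subunit of ribonucleotide reductase, fell to 124 ± 35.9 CPM from 242 ± 21.7 CPM.

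Core macrophage genes rose in 7 and fell in 4 of 18 members, or in 12 and 4 adjusted over the list alone. Adgre1, which encodes F4/80 (chromosome 17, 57358691 to 57483527), stood at 4015 ± 534 CPM against 1751 ± 55.6 CPM, the Fc receptor Fcgr1 at 335 ± 35.3 CPM against 86.2 ± 4.61 CPM, the sialoadhesin Siglec1 at 96.3 ± 20.4 CPM against 18.6 ± 2.38 CPM, and the CSF-1 receptor Csf1r at 3017 ± 63.2 CPM against 2119 ± 47.9 CPM. Lgals3 fell, with a log2 fold change of -0.61, and lysozyme Lyz2 did not pass, at 25681 against 23319 CPM. The list passed as higher (adjusted p = 0.00794, and adjusted p = 0.263 with an estimated correlation). Complement and efferocytosis genes rose in 11 and fell in 3 of 20 members, and in 11 and 6 adjusted over the list alone (adjusted p = 0.00794, and adjusted p = 0.263 with an estimated correlation). Among those that rose were the 3 chains of C1q, with log2 fold changes of 3.17 for C1qa, 2.15 for C1qb and 2.17 for C1qc, and C1qb (chromosome 4, 136880129 to 136886187) reached 2046 ± 255 CPM against 460 ± 34.3 CPM. Genes of fatty acid synthesis and targets of the sterol sensor LXR rose in 6 and fell in 0 of 18, with the same counts adjusted over the list alone (adjusted p = 2.95e-04, and adjusted p = 0.113 with an estimated correlation). Those that rose included the lipid transfer protein Pltp, at 224 ± 25.9 CPM against 11.3 ± 3.46 CPM, the cholesterol exporters Abca1 and Abcg1, with log2 fold changes of 2.15 and 0.88, and Apoe (chromosome 7, 19696109 to 19699188), at 7721 ± 2168 CPM against 814 ± 248 CPM. The fatty acid synthesis gene Acly stood at 337 against 293 CPM and did not pass. Fasn, Acaca, Elovl5, Elovl6 and Srebf1 did not pass either, with log2 fold changes of -0.09, 0.16, -0.03, -0.14 and 0.07. The desaturase Scd2 rose, with 1.11. The rise of this list is thus not a general rise of fatty acid synthesis genes.

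**Figure D2:**
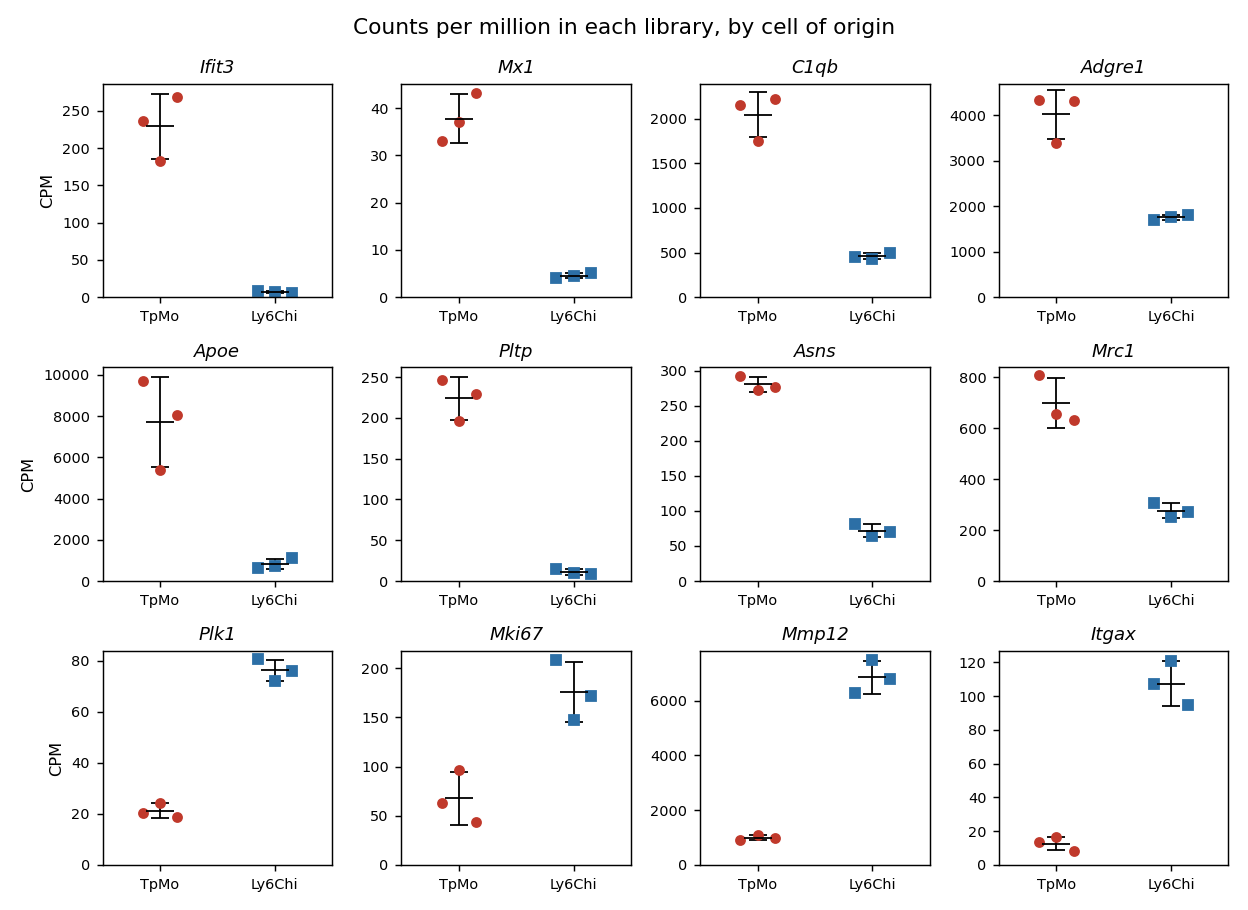
CPM of 12 genes in each library on linear axes that start at 0, with circles for the 3 TpMo-derived and squares for the 3 Ly6Chi-derived libraries, and bars for mean ± SD. In each panel all libraries of one group lie apart from those of the other, with Mmp12 at 989 against 6844 CPM and Ifit3 at 229 against 7.31 CPM.

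Beside the mitotic list, the lists of lysosomal, antioxidant, lipid-associated macrophage and osteoclast genes passed as lower in TpMo-derived macrophages. Lysosomal genes fell in 13 and rose in 4 of 39 members, and fell in 14 and rose in 5 adjusted over the list alone. The protease Ctsd fell, with a log2 fold change of -0.45 ± 0.04 (SE), and the protease Lgmn rose, with 1.20 ± 0.08 (SE). Ctsb, the most abundant member, stood at 28033 against 29070 CPM and did not pass. The median log2 fold change of the list was only -0.16. The list's call (adjusted p = 0.0245) was lost without TpMo-derived replicates 2 or 3 (adjusted p = 0.0658 and 0.0647), after a correction for GC content and length (adjusted p = 0.0568), and with adjusted p = 0.183 with an estimated correlation. Targets of the antioxidant regulator NRF2 fell in 10 and rose in 2 of 24, and fell in 13 and rose in 2 adjusted over the list alone, with the peroxiredoxin Prdx1 at 2649 ± 271 CPM against 4109 ± 570 CPM and the cystine transporter Slc7a11 at 3.42 ± 0.185 CPM against 22.7 ± 10.3 CPM (list adjusted p = 9.71e-04, and adjusted p = 0.263 with an estimated correlation). Hmox1 stood at 2718 against 3032 CPM and did not pass. Lipid-associated macrophage genes fell in 9 and rose in 2 of 21, or 10 and 2 adjusted over the list alone (list adjusted p = 0.00924, and adjusted p = 0.256 with an estimated correlation). Gpnmb, Itgax and the proton pump subunit Atp6v0d2 were among those that fell. Of the lipid-handling members, Apoe and Lpl rose (log2 fold changes 3.25 and 0.63) and Cd36 fell (-0.50). Plin2, Lipa, Npc2, Nceh1, Fabp4 and Fabp5 did not pass. Osteoclast and giant cell genes fell in 5 and rose in 2 of 12, or 7 and 2 adjusted over the list alone. That list had a median of -0.34 but a mean of 0.09, which Mmp9 raised, and its call (adjusted p = 0.0258) was lost without TpMo-derived replicate 1 or Ly6Chi-derived replicate 1 (adjusted p = 0.0534 and 0.0526) and with adjusted p = 0.205 with an estimated correlation.

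Of the stress and metabolic lists, those of the unfolded protein response, of glycolysis and hypoxia and of immediate early and heat shock genes passed as higher in TpMo-derived macrophages. Genes of the unfolded protein response rose in 14 and fell in 0 of 20, or 15 and 0 adjusted over the list alone. Among them the asparagine synthetase Asns stood at 281 ± 10.6 CPM against 71.6 ± 9.39 CPM, the glutathione-degrading enzyme Chac1 at 26.4 ± 2.53 CPM against 2.66 ± 1.1 CPM, and the chaperone Hspa5 at 2348 ± 17.6 CPM against 1603 ± 78.8 CPM (list adjusted p = 2.25e-08, and adjusted p = 0.0854 with an estimated correlation). Glycolysis and hypoxia genes rose in 10 and fell in 3 of 27, or 14 and 4 adjusted over the list alone, with log2 fold changes of 0.44 for Pgk1 and 0.49 for Gpi1 and of -1.29 for P4ha2 (list adjusted p = 0.00209, and adjusted p = 0.113 with an estimated correlation). Immediate early and heat shock genes, which can also rise when cells are harvested, rose in 8 and fell in 0 of 22, or 10 and 0 adjusted over the list alone. Zfp36 and Fos had log2 fold changes of 1.56 and 1.03 (list adjusted p = 1.06e-05, and adjusted p = 0.113 with an estimated correlation). Ribosomal protein genes rose in 8 and fell in 0 of 46, or 13 and 0 adjusted over the list alone (adjusted p = 2.25e-08, but adjusted p = 0.0587 with fry and 0.392 with an estimated correlation). Their most abundant members, Rplp0 and Rpl4, did not pass (log2 fold changes -0.11 and 0.08). Mitochondrially encoded transcripts did not pass (adjusted p = 0.0822, 2 higher and 0 lower of 12, also adjusted over the list alone, but called higher with a filter of at least 5 CPM in 3 samples and without Ly6Chi-derived replicate 2, with adjusted p = 0.0420 and 0.0343), and their share of counts was 1.46 to 1.51% in TpMo-derived and 1.20 to 1.35% in Ly6Chi-derived libraries.

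Of the lists of secreted factors and activation states, 3 passed as higher in TpMo-derived macrophages. Inflammatory cytokines and NF-kB targets rose in 6 and fell in 0 of 17, with the same counts adjusted over the list alone, and Tnf stood at 101 ± 19.1 CPM against 50.0 ± 0.758 CPM (list adjusted p = 0.0185, adjusted p = 0.0672 without TpMo-derived replicate 1, and adjusted p = 0.263 with an estimated correlation). Chemokines rose in 3 and fell in 1 of 14, or 5 and 2 adjusted over the list alone, with Cxcl16 and Pf4 higher and Ccl2 lower (log2 fold changes 1.28, 2.34 and -0.82). That call (adjusted p = 0.00924) was lost without TpMo-derived replicate 3 (adjusted p = 0.0660), with a filter of at least 5 CPM in 3 samples (adjusted p = 0.0940), and with adjusted p = 0.337 with an estimated correlation. Alternative activation genes rose in 5 and fell in 1 of 15, with the same counts adjusted over the list alone. The mannose receptor Mrc1 stood at 698 ± 97.2 CPM against 276 ± 28.5 CPM, and the transcription factor Egr2 fell, with a log2 fold change of -1.24 (list adjusted p = 0.0230, adjusted p = 0.0610 without TpMo-derived replicate 3, and adjusted p = 0.205 with an estimated correlation).

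**Figure D3:**
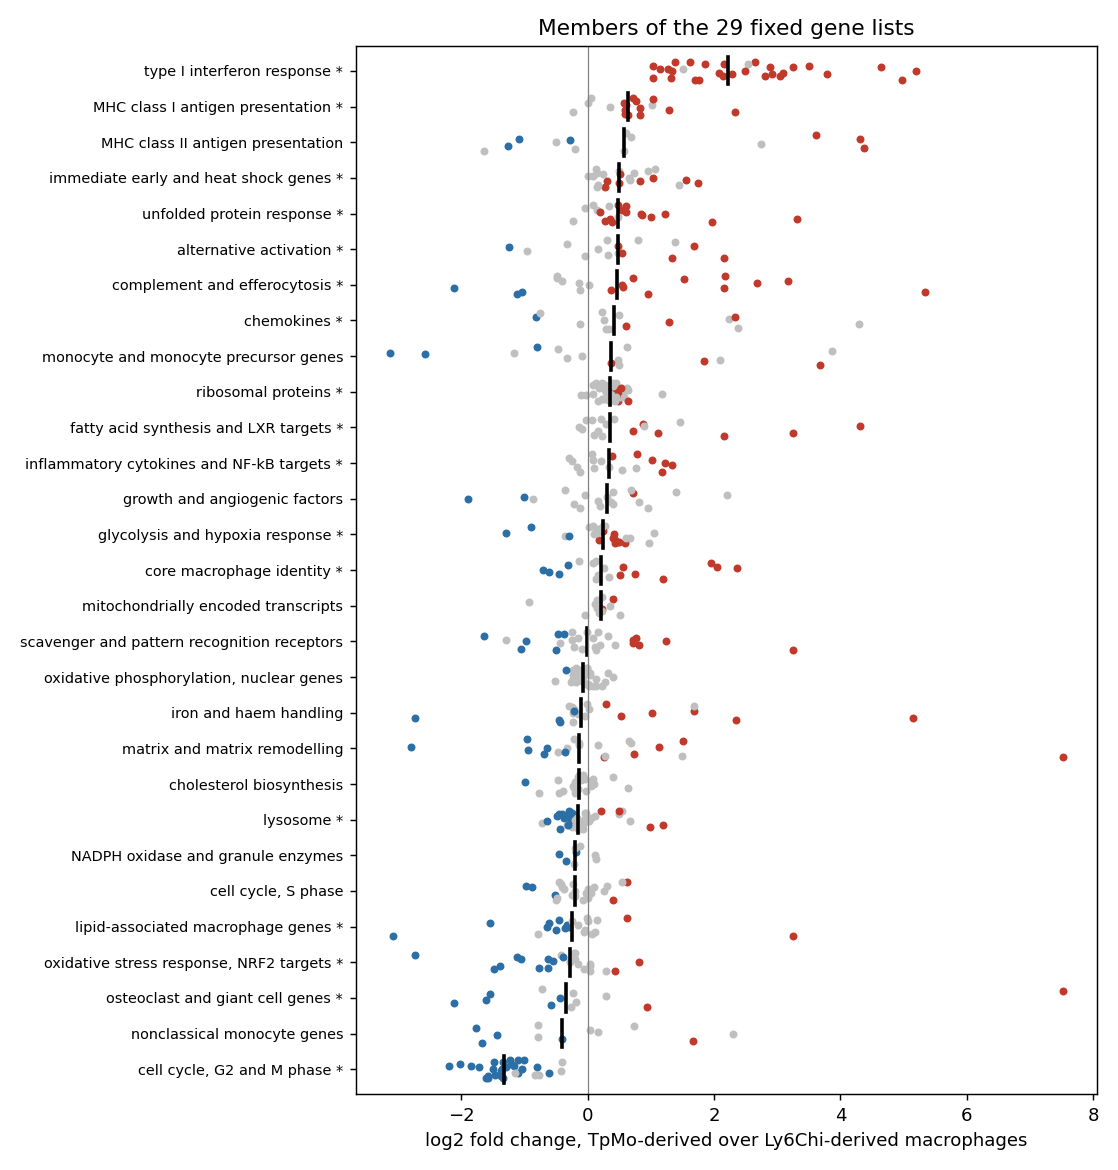
Log2 fold change of each tested member of the 29 gene lists, with positive values for higher in TpMo-derived macrophages, coloured points for members with an adjusted p under 0.05, grey points for the others, black bars for list medians and asterisks for the 17 lists that passed camera. Interferon response genes lie highest, with a median of 2.22, and G2 and M phase genes lowest, with a median of -1.32.

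The remaining lists did not pass. Monocyte and precursor genes went both ways, with 3 higher and 3 lower of 15 (adjusted p = 0.807, and 4 and 3 adjusted over the list alone). Ly6c2, the gene of the sort marker Ly6C, was too low to test, with 18 counts in all over the TpMo-derived and 2 over the Ly6Chi-derived libraries. Ccr2, the monocyte chemokine receptor, stood at 5.61 ± 1.69 CPM against 3.98 ± 1.93 CPM and did not pass (adjusted p = 0.588). Cxcr4, the receptor that retains cells in marrow, fell to 0.771 ± 0.404 CPM from 4.57 ± 0.420 CPM (log2 fold change -2.57 ± 0.56 SE, adjusted p = 0.0142). That call was lost without Ly6Chi-derived replicate 2 or 3 (adjusted p up to 0.0614). Nonclassical monocyte genes rose in 1 and fell in 4 of 11 (adjusted p = 0.159, and 1 and 6 adjusted over the list alone). Matrix genes rose in 5 and fell in 6 of 21, or 8 and 6 adjusted over the list alone, with a median of -0.13 and a mean of 0.32 (adjusted p = 0.903). Scavenger and pattern recognition receptors rose in 6 and fell in 6 of 27, also adjusted over the list alone, with Marco at 115 ± 35.5 CPM against 12.03 ± 1.004 CPM and the beta-glucan receptor Clec7a at 41.4 ± 3.16 CPM against 129 ± 12.7 CPM (adjusted p = 0.903, median -0.01, mean 0.05 and test direction up). Iron and haem genes rose in 6 and fell in 4 of 20, or 6 and 6 adjusted over the list alone, and the transferrin receptor Tfrc stood at 279 ± 25.6 CPM against 138 ± 4.14 CPM (adjusted p = 0.866, median -0.10, mean 0.37 and test direction up). Growth and angiogenic factors rose in 1 and fell in 2 of 19, or 2 and 2 adjusted over the list alone (adjusted p = 0.400). NADPH oxidase and granule genes fell in 3 and rose in 0 of 8, or fell in 4 and rose in 1 adjusted over the list alone (adjusted p = 0.103). Cholesterol biosynthesis genes fell in 1 and rose in 0 of 24, also adjusted over the list alone (adjusted p = 0.101, but called lower without TpMo-derived replicate 2 or Ly6Chi-derived replicate 2, with adjusted p = 0.00384 and 0.0340). Nuclear genes of oxidative phosphorylation fell in 1 and rose in 0 of 34, and in 0 and 0 adjusted over the list alone (adjusted p = 0.322).

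Markers of other cell types were mostly at or near 0. Of 23 neutrophil markers 11 had no count in any library, as had 7 of 20 dendritic cell, 11 of 16 B cell, 13 of 18 T, NK and innate lymphoid cell, 14 of 19 mast cell, basophil and eosinophil, 5 of 15 stem and progenitor and 13 of 18 stromal and endothelial markers. Of the erythroid and megakaryocytic markers, 17 of 18 were in the table and 9 had no count. A few members were abundant and changed. Cadm1 and Bst2 of the dendritic cell list rose, with log2 fold changes of 1.12 and 1.70, and Bst2 also belongs to the interferon list. The eosinophil chemokine receptor Ccr3 rose to 64.1 ± 8.8 CPM from 15.2 ± 2.36 CPM, the platelet factor Pf4 to 197 ± 70.0 CPM from 38.9 ± 7.84 CPM and the stem cell factor Kitl to 62.6 ± 3.36 CPM from 20.3 ± 7.11 CPM. The progenitor marker Cd34, which moved with the mitotic genes, fell to 4.61 ± 2.56 CPM from 40.6 ± 9.25 CPM. Il7r fell, with a log2 fold change of -0.80, Vwf with -1.36 and the neutrophil collagenase Mmp8 with -0.94. Cd4 rose to 6.22 ± 3.38 CPM from 0.104 ± 0.179 CPM (adjusted p = 0.0064), where Ly6Chi-derived replicate 3 held all 10 counts of that group. Pecam1, at 0.880 against 0.0207 CPM (adjusted p = 0.0356), lost its call without any 1 of the 6 libraries (adjusted p up to 0.150).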

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

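The correction for GC content and length, and the list test with library sizes alone, were chosen after seeing the data, and the other alternatives before. The 1620 changed genes numbered 1617 to 1852 under 3 other scalings, limma-voom with and without weights, other gene filters and the added correction, and at least 1498 of the original calls were kept there, each with the same sign. With library sizes alone 737 rose and 902 fell, so that 45.0% were higher against 53.0%. The Wald test of DESeq2 called 2383 genes, 1207 higher and 1176 lower, with 21503 genes entering it, and the cause was not tested. In the simulated counts DESeq2 made 29 false calls against 5 for edgeR, and 14 against 1 with no gene changed. It also recovered more of the genes changed 2-fold there, 58.2% against 43.3%. A test against a 1.5-fold change called 317 genes, 191 higher and 126 lower, since it asks for a larger change, and an adjusted p under 0.01 left 785, 454 higher and 331 lower. Leaving out each library in turn gave 976 to 1492 genes, 531 to 750 higher and 445 to 742 lower, with 1 sample fewer. The total moved by over 1.5 times without TpMo-derived replicate 3 (1074) and without Ly6Chi-derived replicates 1, 2 and 3 (1058, 976 and 1062). The 17 lists called became 0 with an estimated correlation in camera, with 7 lists at an unadjusted p under 0.05 there. Fry called 16, or 27 with direction ignored. A higher correlation is not the whole reason for the 0 calls. With an estimated correlation, camera also takes its p-values from the few residual degrees of freedom of the libraries, not from the number of genes. The share of each was not tested. For the unfolded protein response the estimate was -0.0401, under the preset of 0.01, yet the unadjusted camera p rose from 3.11e-09 to 0.00294. Estimates were also under the preset for the alternative activation, LXR, lysosome, glycolysis and osteoclast lists, but reached 0.707 for G2 and M phase genes. The lists called were 14 to 19 when a library was left out. The number was 16 or 17 under fry, DESeq2 size factors, library sizes alone, the stricter filter and the added correction, and no called list changed direction. Of 137 named genes called, 24 lost the call in at least 1 fit without a library and 11 in at least 1 other alternative, apart from the 64 not called against a 1.5-fold change, and 0 changed sign. Pecam1, Aldoa, Canx, Cybb and Ncf4 lost it most often. Scaling to the spike-ins was not run, since the table used holds 0 such rows. No paired analysis was possible because the labels give the libraries no shared replicate numbers. Depth limits genes under about 0.126 CPM, the level of 3 counts in the shallowest library, or somewhat higher because both mates of a pair were counted.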

Other observations

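The lists in this part were composed after the data had been seen, apart from the fixed lists named above, and the tests of dendritic cell and progenitor transcripts, of the S phase list and of the other tRNA synthetases were chosen only after results of those genes or of the pattern had been seen. Genes of amino acid synthesis and a set of cytosolic tRNA synthetases were higher in TpMo-derived macrophages. Of 12 tested genes of serine, glycine, one-carbon and related amino acid synthesis, 9 rose and 0 fell, with a median log2 fold change of 1.24. Asns rose by 1.97 on that scale, Phgdh, the first enzyme of serine synthesis, by 1.66, Mthfd2, a mitochondrial folate enzyme, by 1.42, and Shmt2 by 1.19. Of 12 cytosolic tRNA synthetases known as targets of ATF4, the transcription factor of the amino acid response, 11 rose and 0 fell, from 0.34 for Sars to 1.1 for Cars, and Wars did not pass. Of 8 other cytosolic synthetases 3 rose, and of 17 mitochondrial ones 1 rose, with 0 lower in either set and medians of 0.21 and 0.11. Amino acid transporters went both ways, with 6 higher and 2 lower of 11. Slc7a5, Slc1a4 and Slc7a1 rose by 2.36, 2.54 and 1.71, whereas the cystine transporter Slc7a11, itself an ATF4 and NRF2 target, had a log2 fold change of -2.73 and the lysosomal transporter Slc36a1 one of -1.57. Camera gave adjusted p = 5.93e-10 for the synthesis genes, 2.40e-10 for these synthetases and 0.0143 for the transporters, 0.0191 for the other cytosolic and 0.184 for the mitochondrial synthetases over 6 such lists (adjusted p = 0.0220, 0.0397, 0.0806, 0.0806 and 0.381 with an estimated correlation), which is no independent evidence, since the first members had drawn attention to them.

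Interferon-inducible GTPases, which act against intracellular pathogens, rose in 10 and fell in 0 of 12 tested members, with a median log2 fold change of 1.604 (camera adjusted p = 1.05e-10, and adjusted p = 0.0220 with an estimated correlation). Irgm1 rose by 1.35 and Gbp2 by 1.68. Iigp1 had 525 counts over the TpMo-derived and 0 over the Ly6Chi-derived libraries. It was 63.7-fold higher when the latter were set to the floor of 3 counts per library. Because both mates of a pair were counted, that value is no strict lower bound. With Iigp1 at that value the median is unaffected. The interferon genes themselves were not detected. All 19 type I, II and III interferon genes looked up had 0 counts in every library, under the same floor of 3 counts per library, or 0.0908 to 0.126 CPM. Reads shared between the near-identical Ifna genes were not counted, a limit that does not apply to Ifnb1 or Ifng.

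The first pattern weighed is the higher interferon response. Dendritic cells can carry such transcripts, and of the 19 members of their list outside the interferon list 1, Cadm1, was called higher in TpMo-derived macrophages (a share of 0.0526), while 7, among them Siglech, Flt3, Ccr7, Clec9a and Cd209a, had no count in any library. The cultures began from sorted cells, which does not by itself exclude such a source. Bst2, Cd74, H2-Ab1 and H2-Aa rose as well, although the MHC class II list went both ways. The level that a small share of dendritic cells would bring is not known from these data, so these cells are not excluded. After removal of each library's trend with GC content and length, the list's median was 2.22, above the bound of 1.1 set from the uncorrected median, so that such a trend is not the whole cause. The cell of origin, which is the group itself, stays open and untested, beside any difference between the cultures that the labels do not record, such as the CSF-1 concentration or an interferon-inducing contaminant.

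The second is the lower level of G2 and M phase genes. Of the 15 members of the stem and progenitor cell list, 2, Cd34 and Procr, were called higher in the Ly6Chi-derived group (a share of 0.133), although Procr lost its call without TpMo-derived replicate 1 or 3 or Ly6Chi-derived replicate 2 or 3 (adjusted p up to 0.109), Kit stood higher in the TpMo-derived group (2.15 against 0.145 CPM, adjusted p = 0.115) and 5 had no count in any library. The cultures began from cells sorted as mature Ly6Chi monocytes, and the granule genes Mpo, Prtn3 and Ctsg had no count, but Elane had 8 counts, all in Ly6Chi-derived replicate 3, and myeloid progenitors left in those cultures are not excluded. The median stayed at -1.30 after the GC and length correction, past the bound of -0.66 set from the uncorrected value. A smaller share of cycling cells in the TpMo-derived cultures may account for it, but the S phase list had an adjusted p of 0.159, with Pcna and Mcm6 higher and Rrm2, Cdc6 and Chaf1b lower (3 higher and 6 lower adjusted over the list alone), and so does not decide between that and a different passage through mitosis.

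The third is the amino acid response. After the GC and length correction the ATF4-target synthetases had a median of 0.79, above the bound of 0.35. An equal rise of all cytosolic synthetases would raise the 8 not known as ATF4 targets as much, but their median was 0.21 against 0.74, and an exact permutation test over genes, which are not independent replicates, gave p = 0.00469 (two-sided, 125970 arrangements). A smaller general rise is not excluded, since camera called these 8 higher, Farsb, Kars and Vars of them rose, and the split into targets rests on general knowledge and was made after the targets' values had been seen. Atf4, Chac1, Trib3 and Ddit3 were higher too and Slc7a11 lower, but the activity of ATF4 was not measured. The unfolded protein response list rose in 14 and fell in 0 of 20 members, with log2 fold changes of 0.55 for Hspa5 and 0.60 for Pdia6. These data therefore do not tell an amino acid response from an unfolded protein response. CSF-1 concentration, cell density, medium renewal and cell of origin stay open as well. The labels give 1 base medium but none of the first 3, and the last is the group itself.

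Of the 10 ways to split the 6 libraries into 3 and 3, the real one (1 of 10) was the one with the most changed genes, 1620 by the edgeR test against at most 0 in any other split (3208 against at most 354 at an unadjusted p under 0.05), and with the most called lists, 17 against at most 9. With 10 splits no share under 0.05 can be reached. The other splits mixed the groups and called 1, 2, 0, 5, 7, 9, 6, 7 and 4 lists, with 0 genes called in each. Camera at its preset correlation can thus call lists where no gene is called, which limits the reading of the 17 calls. Each of these splits held the groups in unequal shares and so kept part of their difference. They therefore do not show whether such list calls are false. In simulated counts with no gene changed, camera at the preset called 0 of 29 lists. Those genes were drawn independently, so the simulation does not test the effect of correlated genes.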
